A study of Mus musculus with 141 samples.

How the data were processed

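RNA was sequenced from naive CD4 T cells (CD4+CD25-CD44lo, sort purified, per the labels) of C57BL/6 mice and from the same kind of cells at 9 times from 0.5 to 72 h of stimulation, in 47 groups of 3 libraries. Per the labels the libraries of a group are biological replicates; which mice or cultures they share is not given in the sources used here. The submitters' processing notes name TopHat, HTSeq and the builds mm9 and GRCh37, the last a human build, without versions, settings or which step used which; the reference behind the gene symbols is not given in the sources used here. The deposited table is named for read counts, but its values are CPM: every column sums to the same total, and dividing each column by its smallest value gave whole numbers for 100% of values (tolerance 0.001). It had 46517 genes, and 0 columns were left out. All 37 mitochondrial genes (prefix mt-) had 0 reads, so the share of mitochondrial reads could not be used as a measure of cell damage. The whole numbers were taken as reads, giving 16 to 47.1 M reads per library, so 1 read is well under 1 CPM in each library. Only symbols are given, so no positions are reported.

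Before the data were examined, the groups, comparisons, 25 gene lists, the rule for named genes, the tests and most alternatives were fixed. The plan assumed reads and edgeR; as the unit was CPM, the test was limma-trend on log2 of TMM-scaled CPM plus 0.5, and edgeR and DESeq2 on the recovered reads became alternatives. Genes with at least 1 CPM in at least 3 libraries were tested: 14695 in courses 1 to 3, 14859 in courses 4 to 6 and 15328 over all courses, with 38, 56 and 94 residual degrees of freedom. All groups of a set entered a single fit. Benjamini-Hochberg adjustment ran over all genes of a comparison, and a gene was called at an adjusted p under 0.05; all adjusted p values printed for genes are from limma unless another tool is named. The log2 of a value plus 0.5 understates the change of genes near 1 CPM. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and the package data.table at 1.17.8.

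The comparisons were no cytokines against naive 0 h at 2, 24 and 72 h; IL6 and TGFb against no cytokines at each of 9 times, and the difference of that effect between 72 and 2 h; the 3 cocktails of courses 4 to 6 against each other as means over 0.5 to 2 h, 4 to 12 h and 24 to 72 h; each cocktail against IL6 and TGFb from 24 to 72 h with each set's own 0 h subtracted; and the 0 h groups against each other. Cocktails and IL6 with TGFb were never grown in the same courses, so course set and cytokine cannot be told apart without that subtraction, and a difference between the sets that arose in culture stays in it. Whether libraries of a course pair was checked from the correlation over genes of their deviations from the group means. It was above 0.1 in all 3 courses at 0.5, 1, 2, 4 and 12 h (lowest 0.126, 0.388, 0.405, 0.234 and 0.306) but not at 6, 24, 48 and 72 h (lowest 0.021, 0.042, -0.099 and -0.391) or over all times of a cocktail comparison (lowest -0.353). At 4 and 72 h it was above 0.1 in all 3 courses of every cocktail comparison (lowest 0.317 and 0.432). Course was left out of the fit and added as a block in alternatives, among cocktails also as a block at each time. Replicates were not copies: squared differences between them averaged 2.96 to 265 times Poisson noise per gene (median 11.9), and 0 columns were identical.

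The 25 lists were Th17 core (16 genes), IL-6 and STAT3 response (15), TGF-beta and SMAD response (19), Th1 (14), Th2 (11), Treg (13), Tfh (11), Th17 pathogenic-associated (16), Th17 non-pathogenic-associated (7), NF-kB and IL-1 response (17), cytokine receptors (22), AhR (6), naive and quiescence (14), immediate early activation (18), cell cycle (20), glycolysis and hypoxia (17), cholesterol (17), interferon response (18), unfolded protein and amino acid stress (11), heat shock (9), and markers of B cells (10), CD8 T cells (2), myeloid cells (13), NK and gamma-delta T cells (8) and erythroid cells and platelets (11). They were written from general knowledge and overlap: 8 genes each of Th17 core, IL-6 and pathogenic-associated, 12 of cytokine receptors, 7 of Th1 and 5 of non-pathogenic-associated are also in another list. Lists were tested against all other genes with camera at a preset correlation of 0.01, and again with the correlation estimated. Named genes were called genes with a mean of at least 5 CPM and no overlap between the libraries of both groups (for means over 3 times, the same sign at each); for 3 against 3 libraries chance gives such separation for 10% of genes. Clone and predicted-gene symbols were passed over. From these came the most extreme genes in each direction (4 or 5, or 1 or 2 in minor comparisons), all Th17 core genes at 72 h and in the late cocktail comparisons, and up to 4 members of each other list; 3 genes that the rule picked are not reported here. Near-identical genes share reads that HTSeq may have dropped or split, so values of Hspa1b, the globin gene Hbb-bs, Ms4a4b and Ms4a4c, Mndal and Ifi203, and the Gbp genes are less certain.

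Alternatives changed a single choice at a time, with the filter and scaling applied anew to the libraries of each fit: RLE in place of TMM scaling, no filter, a fit of only the libraries compared, a course block, each course left out in turn, DESeq2, and an estimated correlation for lists. Chosen after seeing the data were no TMM scaling, pseudocounts of 0.1 and 1, edgeR, a fit without the course 1 libraries at 48 and 72 h without cytokines, a course block at each time among cocktails, and a course block fitted to only the libraries compared. The last changed 2 choices together, as did edgeR, whose own filter kept 17640, 17990 and 18574 genes. Where a course left out leaves 2 libraries in a group, the spread is pooled over all groups. The calls were also counted for other splits of the libraries, for cocktails also with exchanges only within a course and time. The method was tested on simulated data with 200 changed genes. Simulated libraries were drawn independently, with no course effect and no outlying library, so the shares found may not carry over to the real libraries. For 3 against 3 libraries at 72 h it found 39.7%, 76.6% and 94.8% of 1.5-fold, 2-fold and 4-fold changes, with 134 calls of which 5 were of unchanged genes. For a late cocktail comparison it found 91.8%, 94.7% and 100% (185 calls, 11 of unchanged genes), and for a comparison relative to 0 h 51.6%, 67.2% and 88.9% (133 calls, 4 of unchanged genes). On the 72 h simulation edgeR found 134 of the changed genes and called 3 unchanged ones, and DESeq2 found 140 and called 16.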

Results

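Transcript levels were measured by RNA sequencing in mouse helper T cells during 72 h of culture. Naive CD4 T cells, which have not yet met antigen, came from spleen and lymph nodes of C57BL/6 mice, an inbred strain, and were stimulated through the T cell receptor and CD28 with plate-bound antibodies. Cells were collected before stimulation (0 h) and at 9 times from 0.5 to 72 h. The labels number the replicates as courses. Courses 1 to 3 received no cytokines or IL6 with TGFb, the pair that starts the Th17 fate, whose cells make interleukin 17. Courses 4 to 6 received IL6 and TGFb together with IL1b, with IL21, or with both. The libraries formed 47 groups of 3, with 57 libraries in courses 1 to 3 and 84 in courses 4 to 6, and each set of courses had its own 0 h group. Counted reads per library ran from 16 to 47.1 M (median 25.4 M), from 16.1 to 35 M in courses 1 to 3 and from 16 to 47.1 M in courses 4 to 6. Gene changes are log2 fold changes ± SE from limma, with 3 libraries per group, and levels are TMM-scaled CPM ± SD. The SE of a gene comes from a spread pooled over all groups of its fit, so it does not measure the spread of the groups compared.

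The first question was what receptor and CD28 stimulation did without added cytokines. By 2 h, Il2, which encodes the T cell growth factor interleukin 2, had risen by 7.54 ± 1.05 (adjusted p = 2.55e-08), from 2.11 CPM to 367 ± 56 CPM. The orphan nuclear receptor genes Nr4a2 and Nr4a3, induced by receptor signalling, rose by 7.50 ± 0.54 and 7.43 ± 0.57, and Atf3, a stress-induced transcription factor gene, by 7.11 ± 0.46. Of the 18 immediate early activation genes measured, 14 were higher and 3 lower; the lower ones, Jun, Fos and Junb, chosen after their values were seen, encode parts of the AP-1 factor, and Fos stood at 723 ± 12.8 CPM at 0 h. Of 17 NF-kB and IL-1 response genes 13 rose, with the cytokine gene Tnf up by 5.10 ± 0.15. Stress genes of amino acid shortage rose too, 10 of 11 on the list, among them Chac1, a glutathione-degrading enzyme gene, by 4.24 ± 0.25 and Sesn2, an inhibitor of growth signalling, by 3.95 ± 0.32. In the other direction, 16 of 18 interferon response genes fell, including the interferon brake Usp18 (-3.17 ± 0.27) and Ifit2 (-3.14 ± 0.20), an antiviral gene. The largest falls among named genes were in Slc16a5, a transporter gene (-4.51 ± 0.29), Slfn5, a growth regulator (-3.98 ± 0.21), Ifit1bl1, an interferon-induced gene (-3.98 ± 0.48), and Dtx1, a Notch pathway gene (-3.97 ± 0.24). Of 14 naive and quiescence genes 9 fell and 2 rose, with Il7r, the receptor for a survival cytokine, at -2.64 ± 0.33.

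At 2 h 10166 of 14695 genes tested changed, 4767 higher and 5399 lower. Without TMM scaling 36.2% of the calls were higher in place of 46.9%, and the median log2 change of all genes was -0.22 in place of -0.04. In camera, a test of a list against all other genes, the immediate early, NF-kB and interferon lists each had an adjusted p of 0.000252, and adjusted p = 0.557, 0.341 and 0.341 with an estimated correlation; the stress list had 5e-04, and adjusted p = 0.328 with an estimated correlation. The interferon count adjusted over the list alone was 17 lower.

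By 24 h without cytokines the replication programme was on. Mcm10, a gene for starting DNA replication, had risen by 6.52 ± 0.32, and all 20 cell cycle genes had risen, with Rrm2, which makes DNA building blocks, at 5.93 ± 0.29 and the cyclin gene Ccna2 at 5.86 ± 0.38. Il2 remained 7.20 ± 1.05 above 0 h, and Ccl4, a chemokine gene, and Bcat1, an amino acid enzyme gene, were up by 7.03 ± 0.90 and 6.76 ± 0.58. Of 17 glycolysis and hypoxia genes 13 were higher and 2 lower (Hk2, the first enzyme of glycolysis, 5.54 ± 0.30), and 14 of 17 cholesterol genes were higher. Of the naive and quiescence genes 11 of 14 fell and 1 rose, with Il7r at -6.42 ± 0.33 and S1pr1, which lets T cells leave lymph nodes, at -5.83 ± 0.65. Interferon response genes stayed below 0 h, 16 of 18, with the regulator Irf7 at -5.98 ± 0.31, and the largest falls were in the chaperone gene Hspa1b (-6.92 ± 1.06) and Pydc4, an interferon-induced gene (-6.59 ± 0.42). By 72 h, cell division genes led: Ccna2 was up by 6.81 ± 0.38, and Aspm, Kif4 and Kif18b, genes of the mitotic spindle, by 6.78 ± 0.28, 6.64 ± 0.24 and 6.61 ± 0.32. All 17 cholesterol genes had risen, with Idi1 at 3.38 ± 0.18 and Hmgcs1 at 3.15 ± 0.13, both enzymes of sterol synthesis. Fos was at -7.42 ± 0.40, and Dtx1 was at -6.96 ± 0.24. Most markers of other blood cells were lower. Of 9 myeloid genes all were lower at 24 h, and 8 were lower and 1 higher at 72 h, with the lysozyme gene Lyz2 at -3.82 ± 0.31 and -4.08 ± 0.31. All 7 red cell and platelet genes were lower at both times, with the globin gene Hbb-bs at -3.96 ± 0.27 and -4.98 ± 0.27. Of 8 B cell genes 6 were lower at 24 h and 4 at 72 h, and of 5 NK and gamma-delta genes 3 were lower and 1 higher at 24 h and 3 lower and 2 higher at 72 h. Of the 2 CD8 genes 1 was higher at 24 h and both were lower at 72 h.

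At 24 h 10681 genes changed (5277 higher, 5404 lower) and at 72 h 9603 (4878 higher, 4725 lower) of 14695. At 24 h camera gave adjusted p = 7.16e-14 for cell cycle (adjusted p = 0.21 with an estimated correlation), 3.48e-07 for interferon (0.21), 0.000729 for both the naive (0.263) and cholesterol (0.391) lists, 0.00193 for glycolysis (0.509), 0.00301 for myeloid (0.263) and 0.00261 for erythroid and platelet genes (0.263). At 72 h the values were 1.56e-18 for cell cycle (0.102), 6.56e-11 for cholesterol (0.13), 4.19e-05 for glycolysis (0.3), 0.000648 for naive (0.233), 9.08e-05 for interferon (0.233), 0.0301 for immediate early (0.606), 0.00203 for myeloid (0.233) and 0.000107 for erythroid and platelet genes (0.187), again with the adjusted p at an estimated correlation in brackets. The naive count adjusted over the list alone was 12 lower at 24 h. The 72 h no-cytokine group was the most uneven of all groups. Its course 1, 2 and 3 libraries lay 0.63, 0.342 and 0.334 (root mean square log2 distance) from the group mean, against a median of 0.158 over the libraries of courses 1 to 3. Courses 2 and 3 were alike there, at 8.26 times Poisson noise, while course 1 differed from them by 240 and 265 times. As the spread is pooled over all groups, the limma SE and adjusted p of comparisons with this group understate its unevenness.

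The next question was when IL6 and TGFb first made a difference. At 0.5 h the chemokine gene Cxcl10, a classical interferon target, was 2.89 ± 0.27 higher than without cytokines (adjusted p = 4.67e-10), and Dusp2, a phosphatase gene that limits MAP kinases, was at -1.45 ± 0.29 (adjusted p = 0.0026; 0.152 without course 2 and 0.207 without course 3). At 1 h Tbx21, which encodes the Th1 regulator T-bet, was up by 5.01 ± 0.61 (adjusted p = 1.9e-08), and Tnfsf11, the gene of the cytokine RANKL, was at -2.39 ± 0.51 (adjusted p = 0.000716; 0.07 without course 2 and 0.0552 without course 3). At 2 h Tbx21 was still 5.07 ± 0.61 higher, at 216 ± 17.2 against 6.46 ± 3.05 CPM. Also up at 2 h were Elovl6, a fatty acid enzyme gene, by 5.02 ± 0.21, Ly6a, the interferon-induced surface marker Sca-1, by 4.95 ± 0.22, the guidance receptor gene Ephb2 by 4.45 ± 0.27, and Gbp5, an interferon-induced GTPase gene, by 4.28 ± 0.37. Of 18 interferon response genes 16 were higher, led by Gbp2 (3.64 ± 0.39) and Rtp4 (3.36 ± 0.41). Of 15 IL-6 and STAT3 response genes 11 were higher, with Batf, an AP-1 family factor needed for Th17 cells, up by 3.66 ± 0.23 and the feedback inhibitor Socs3 by 2.72 ± 0.56. Of the 16 Th17 core genes 6 were higher at 2 h, with Il21, a helper cytokine gene, at 3.09 ± 0.41, Il1r1, the IL-1 receptor, at 2.28 ± 0.30, Maf, a factor for Il10 and Il21, at 2.14 ± 0.31 and Ahr, the aryl hydrocarbon receptor, at 1.67 ± 0.29; Il17a and Il17f were not among them. Il21 and Cxcr5 (3.00 ± 0.24) were also among 3 of 11 Tfh genes that rose.

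Genes that fell at 2 h included Phldb1, a cell cortex gene (-1.99 ± 0.16), Gpr174, a lysophospholipid receptor gene (-1.69 ± 0.25), Id3, an inhibitor of E proteins (-1.60 ± 0.26), Mvk, of sterol synthesis (-1.43 ± 0.16), and Gata3, the Th2 regulator (-1.07 ± 0.16). Lad1, a cytoskeletal gene, Sytl2, a vesicle gene, and Tnfsf14, the gene of the cytokine LIGHT, lost their calls without course 2 and without course 3, with fewer libraries and folds of similar size. Lad1 was at -2.04 ± 0.53, and at -2.22 (adjusted p = 0.0953) and -2.01 (0.147) without these courses. Sytl2 was at -1.89 ± 0.49, then -1.83 (0.154) and -2.06 (0.0635), and Tnfsf14 at -1.74 ± 0.50, then -1.72 (0.239) and -1.80 (0.127). Of 18 TGF-beta and SMAD genes 1 rose and 3 fell at 2 h, and of 17 cholesterol genes 4 fell. Adjusted over the list alone, the 2 h counts were 17 higher for interferon, 2 higher and 5 lower for TGF-beta, and 3 higher and 1 lower for Tfh. The camera values at 2 h were 1.05e-24 for interferon, 3.68e-16 for IL-6 and STAT3 and 1.61e-06 for the 7 Th17 non-pathogenic-associated genes (4 higher), and these 3 held with an estimated correlation (0.000342, 1.62e-05 and 0.0018). Those for Th17 core (2.45e-06), AhR (0.00977; 2 of 6 higher), Tfh (0.0137), cholesterol (0.014), Th1 (0.0487) and Th17 pathogenic-associated genes (0.0487) had adjusted p = 0.0975, 0.0662, 0.349, 0.643, 0.349 and 0.564 with an estimated correlation.

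In numbers, IL6 and TGFb changed 89 genes at 0.5 h (69 higher, 20 lower), 1170 at 1 h (672 and 498) and 1826 at 2 h (821 and 1005). Single courses moved these counts: without course 2 they were 43, 533 and 673, and without course 3 they were 45, 696 and 1018. The libraries of a course tracked each other at these times, and a block for course in the fit gave 101, 1244 and 1939. The same block with only the libraries compared gave 353, 2322 and 4149, at 0.5 h with 166 higher and 187 lower, and without the block that fit gave 21 at 0.5 h.

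From 4 to 24 h few interferon genes passed the test. Il21 was the largest rise among named genes at 4 h (5.49 ± 0.41, adjusted p = 9.78e-14) and at 6 h (4.99 ± 0.41), and Maf at 12 h (6.93 ± 0.31, adjusted p = 1.33e-21). The largest falls were in the chemokine gene Xcl1 at 4 h (-2.52 ± 0.33, adjusted p = 2.7e-07), the adhesion receptor gene Cd226 at 6 h (-3.22 ± 0.32) and Fasl, a death ligand gene, at 12 h (-4.36 ± 0.57, adjusted p = 8.29e-08). Of the 18 interferon response genes 17 were higher at 1 h and 2 at 4 h, and their median log2 change was 1.67 at 1 h, 0.34 at 4 h and 0.16 at 6 h. At 24 h Il17f, a signature cytokine gene of Th17 cells, was up by 8.31 ± 0.72 (adjusted p = 6.77e-13), at 1240 ± 151 against 4.5 ± 4.05 CPM. Il21 (6.71 ± 0.41), Il1r1 (6.69 ± 0.30), Cyp1b1, a target of the aryl hydrocarbon receptor (6.65 ± 0.30), and Maf (6.62 ± 0.31) followed, and 15 of 16 Th17 core genes were higher. Il23r, the receptor that sustains Th17 cells, rose by 4.27 ± 0.19, Ahr by 4.57 ± 0.29, Il9 by 4.27 ± 0.34 and Il22, a barrier cytokine gene, by 2.81 ± 0.24. The TGF-beta list now had 10 of 18 genes higher and 1 lower, with the feedback gene Pmepa1 up by 3.93 ± 0.24. Lower at 24 h were the chemokine genes Ccl3 (-5.60 ± 0.86, adjusted p = 1.35e-06) and Ccl4 (-4.89 ± 0.90), Nrn1, a gene of anergic T cells (-5.20 ± 0.40), Fasl (-4.84 ± 0.57), Cd226 (-4.77 ± 0.32), the cytokine gene Il3 (-3.91 ± 0.44) and Gata3 (-2.97 ± 0.16). Cd8b1, a chain of the CD8 coreceptor, fell by 3.78 ± 0.15 (adjusted p = 3.89e-23). Of 15 Th17 pathogenic-associated genes, linked to inflammatory Th17 cells, 3 rose and 5 fell, so that list split.

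At 24 h all 7 Th17 non-pathogenic-associated genes, 12 of 15 IL-6 and STAT3 genes, 5 of 6 AhR genes, 12 of 22 cytokine receptor genes and 6 of 13 Treg genes were higher, and 1 IL-6, 3 receptor and 2 Treg genes were lower. Adjusted over the list alone, the TGF-beta count was 12 higher and 1 lower and the Treg count 7 higher and 2 lower. Camera gave 1.44e-27 for Th17 core, 1.38e-16 for non-pathogenic-associated, 3.47e-11 for IL-6 and STAT3, 6.5e-09 for TGF-beta, 2.83e-08 for AhR, 8.59e-06 for cytokine receptors, 0.00159 for the 2 CD8 genes and 0.0202 for Treg. With an estimated correlation the Treg list had adjusted p = 0.128 and the other 7 kept a call, the weakest being CD8 at 0.018. The counts were 646 genes at 4 h (401 higher, 245 lower), 677 at 6 h (418 and 259), 1399 at 12 h (795 and 604) and 3844 at 24 h (1988 and 1856). Without course 2 they fell to 229, 278, 736 and 2326, and without course 3 to 347, 390, 827 and 2400. The course block, used at 4 and 12 h where libraries tracked each other, gave 720 and 1473, and 2557 and 4482 with only the libraries compared. Without a block, the fit of only the libraries compared gave 1254, 1779 and 2539 at 4, 6 and 12 h.

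**Figure D1:**
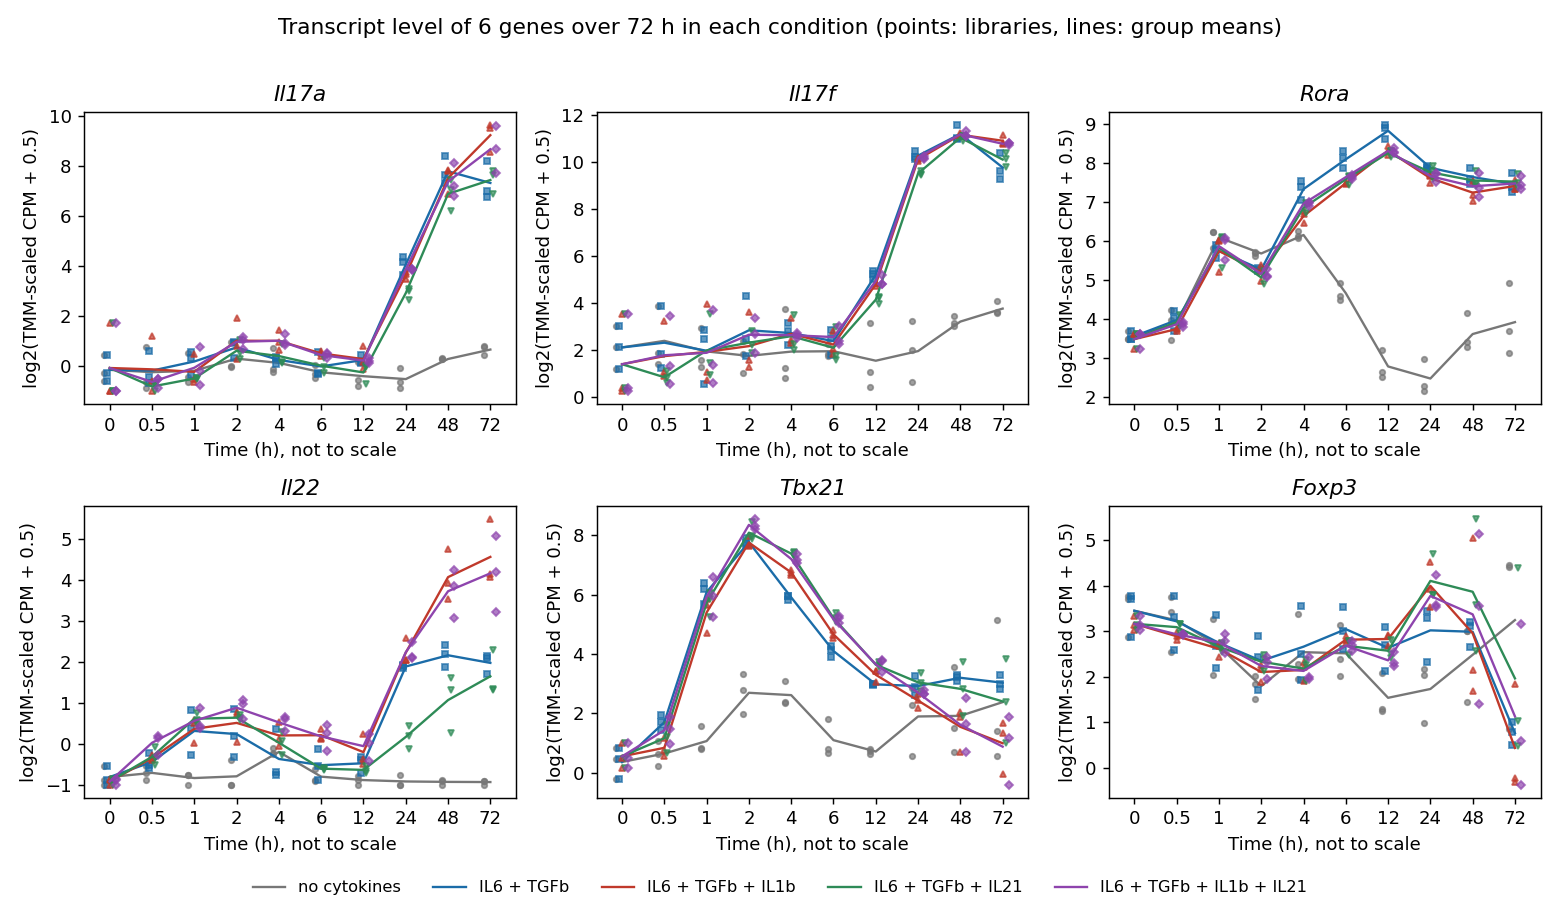
Levels of Il17a, Il17f, Rora, Il22, Tbx21 and Foxp3, as log2 of TMM-scaled CPM plus 0.5, at 0 h and the 9 later times (time axis not to scale). Points are libraries, 3 per group, and lines join group means of the 5 culture conditions; Tbx21 rises early and Il17f late with IL6 and TGFb.

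At 72 h Il17a, the defining cytokine gene, was 6.67 ± 0.39 higher with IL6 and TGFb (adjusted p = 1.24e-18), at 177 ± 104 against 1.08 ± 0.214 CPM without cytokines. Rora, which encodes an orphan nuclear receptor of Th17 cells, was up by 3.54 ± 0.25. All 16 Th17 core genes were higher in limma, among them Il17f (6.00 ± 0.72), Il23r (6.50 ± 0.19), the chemokine gene Ccl20 (6.44 ± 0.30), Maf (6.52 ± 0.31), Ahr (5.67 ± 0.29), Il1r1 (5.48 ± 0.30), Il10 (4.98 ± 0.27), Il24 (3.78 ± 0.16), Irf4 (3.11 ± 0.43) and Il22 (2.91 ± 0.24). Batf was higher by 0.78 ± 0.23 (adjusted p = 0.00398) and lost its call without course 2, at 0.60 (0.215). Ccr6, a homing receptor gene, was higher by 1.36 ± 0.54 (adjusted p = 0.0354) in limma. This rise was not seen in edgeR, at 0.11 (adjusted p = 0.901), or DESeq2, at 0.08 (0.936). In limma it was at 0.43 (0.718) without course 2, 0.65 (0.54) without course 3 and 3.07 without course 1. Its adjusted p was 0.0658 without a filter, 0.0507 without TMM scaling, 0.0548 with a pseudocount of 0.1 and 0.445 with only the libraries compared. The largest rises of all named genes were Il21 (7.19 ± 0.41), Tgm2, a transglutaminase gene (6.98 ± 0.54), Ltb4r1, a leukotriene receptor gene (6.97 ± 0.26), Gap43, known from growing neurons (6.90 ± 0.15), and Cysltr1, a leukotriene receptor gene (6.77 ± 0.34). At 48 h Il17f led (7.98 ± 0.72, adjusted p = 1.16e-12), and Lad1 was the lowest (-6.36 ± 0.53, adjusted p = 1.5e-13).

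At 72 h all 17 glycolysis and hypoxia genes were higher with IL6 and TGFb, with Egln3, a hypoxia-induced oxygen sensor, at 6.21 ± 0.35 and Bnip3, a mitophagy gene, at 3.20 ± 0.28. Of 11 unfolded protein and amino acid stress genes 7 were higher, with Asns, asparagine synthetase, at 2.74 ± 0.32. Of 20 cell cycle genes 7 were lower, including Tyms, of thymidine synthesis (-1.17 ± 0.16), and 4 of 17 cholesterol genes were lower (camera adjusted p = 0.532). Rival fates gave mixed lists. Gata3 was at -3.18 ± 0.16 (adjusted p = 3.2e-21), yet 3 of 8 Th2 genes rose and 1 fell. The Th1 list had 5 higher and 4 lower of 14, with Il12rb2, the IL-12 receptor, at 5.31 ± 0.29. The Treg list had 4 higher and 4 lower of 13, with the adenosine-producing enzyme Nt5e up by 3.19 ± 0.19 and Foxp3, the Treg regulator, at -2.49 ± 0.58 (adjusted p = 4e-04). Foxp3 lost its call without course 2 (adjusted p = 0.125) and with only the libraries compared in the fit (0.123). It varied without cytokines, at 1.3, 21 and 21.5 CPM. Tfh genes were mostly higher (6 of 11, 1 lower), while the Th17 pathogenic-associated list had 7 higher and 4 lower of 15, with Lgals3, the gene of galectin 3, at 3.58 ± 0.37. Interferon response genes, higher at 2 h, were now mostly lower, 12 of 18 with 1 higher, with Isg20, an RNA-degrading antiviral enzyme, at -3.24 ± 0.28, Rtp4 at -2.12 ± 0.41 (adjusted p without course 2 0.0564) and Gbp2 at 2.84 ± 0.39. The largest falls were in Dapl1, a gene of resting T cells (-6.09 ± 0.23), the membrane genes Ms4a4b (-5.88 ± 0.23) and Ms4a4c (-5.42 ± 0.21), and the interferon-inducible genes Mndal (-5.20 ± 0.26) and Ifi203 (-5.14 ± 0.32).

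The remaining 72 h lists gave these results. Of NF-kB and IL-1 genes 8 of 17 were higher and 3 lower, of immediate early genes 9 of 18 higher and 1 lower, and of naive and quiescence genes 4 of 14 higher and 2 lower, with Il7r at 4.23 ± 0.33 and Klf3 at -3.98 ± 0.22. IL-6 and STAT3 genes were 10 of 15 higher, TGF-beta genes 11 of 18 higher and 2 lower, cytokine receptors 11 of 22 higher, AhR genes 5 of 6 higher and 1 lower, and non-pathogenic-associated genes 6 of 7 higher. No heat shock gene of 8 passed the limma test. Among markers of other cell types, 1 of 8 B cell genes was higher and 4 lower, 1 of 2 CD8 genes was lower (Cd8b1, -1.01 ± 0.15), 1 of 9 myeloid genes was higher and 2 lower, 2 of 5 NK and gamma-delta genes were higher (Klrd1, an NK receptor, at 4.82 ± 0.19, and Klrk1, chosen after its value was seen, at 0.99), and no erythroid gene of 7 passed. Adjusted over the list alone, 12 IL-6 genes were higher, TGF-beta had 12 higher and 2 lower, cytokine receptors 11 and 2, Treg 6 and 4, Th1 5 and 5, Th2 3 and 3, cell cycle 6 lower, stress 8 higher and interferon 2 and 12. Camera gave 1.17e-18 for Th17 core, 2.52e-15 for glycolysis, 1.76e-06 for non-pathogenic-associated, 1.51e-05 for IL-6 and STAT3, 0.000145 for AhR, 0.000306 for stress and 0.000849 for TGF-beta, all 7 with a call at an estimated correlation (0.00203, 0.0281, 0.00281, 0.0099, 0.00693, 0.0454 and 0.00982). It gave 0.0011 for cytokine receptors, 0.0134 for Tfh, 0.0143 for immediate early, 0.0155 for interferon and 0.0324 for cell cycle genes, which had adjusted p = 0.0824, 0.285, 0.612, 0.525 and 0.623 with an estimated correlation.

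At 48 h 7791 genes differed (4055 higher, 3736 lower) and at 72 h 6803 (3336 and 3467). Without TMM scaling the higher share of calls was 38% in place of 52% at 48 h, where the median of all genes moved from -0.03 to -0.15, and 38.6% in place of 49% at 72 h. The counts were 4726 at 48 h and 3866 at 72 h without course 2, and 4509 at 72 h without course 3. Without course 1 they rose to 8481 at 48 h and 8250 at 72 h. The course 1 libraries without cytokines stood apart at 48 and 72 h, and without these libraries the counts were 8885 and 8694.

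**Figure D2:**
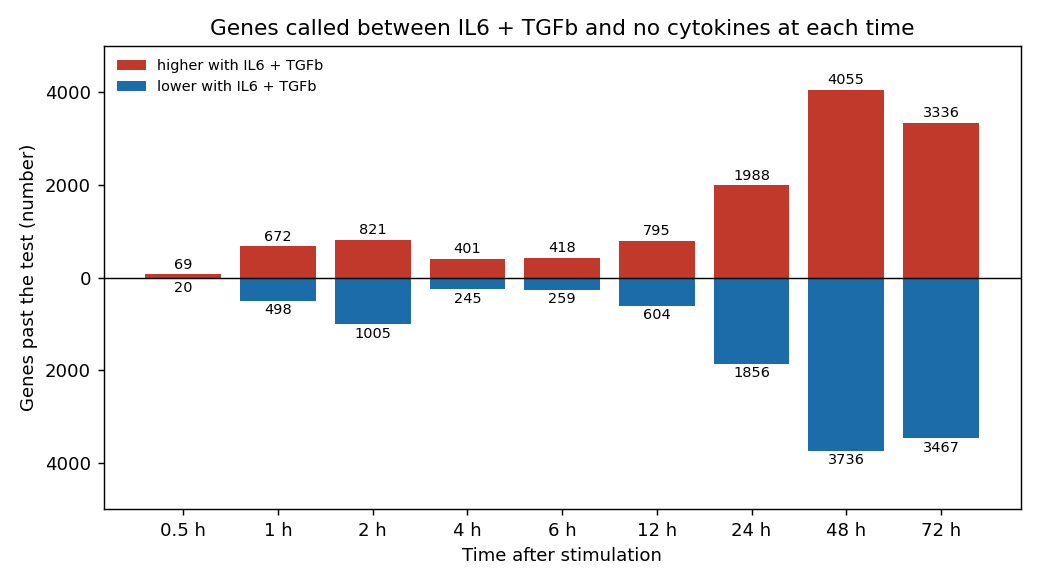
Number of genes higher (above 0) and lower (below 0) with IL6 and TGFb than without cytokines at each of the 9 times, by limma on 14695 genes with 3 libraries per group. The total runs from 89 genes at 0.5 h to 7791 at 48 h.

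**Figure D3:**
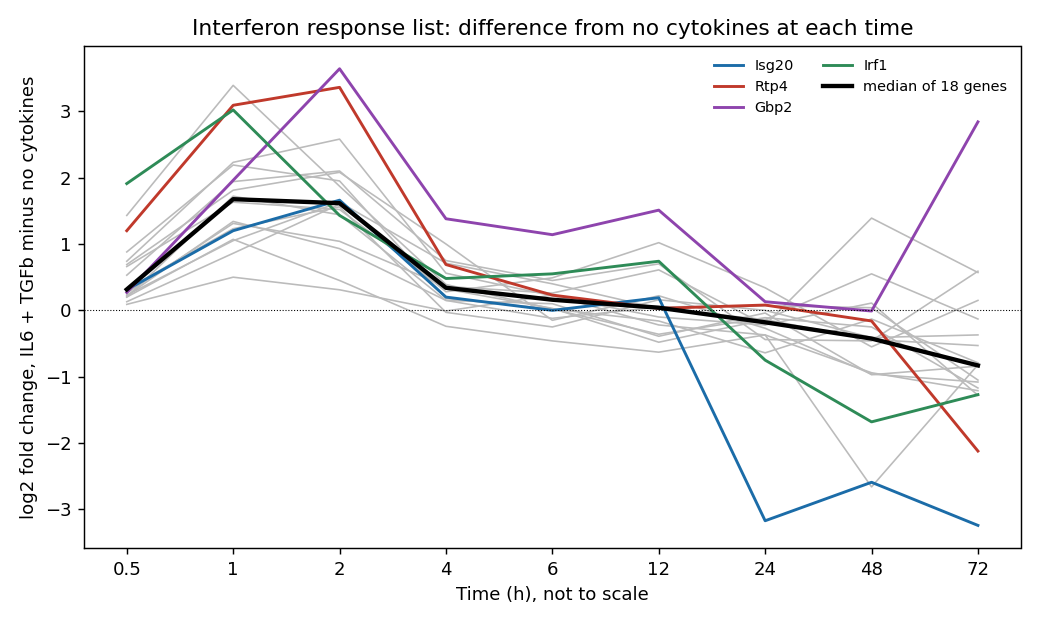
Log2 difference, IL6 and TGFb minus no cytokines, of the 18 interferon response genes at each time, with the median in black and Isg20, Rtp4, Gbp2 and Irf1 in colour. The median is 1.67 at 1 h and -0.83 at 72 h.

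A direct test asked which effects of IL6 and TGFb were not the same at 72 h as at 2 h. Il17a changed by 6.21 more at 72 h, Il23r by 6.49, Ccl20 by 6.36, Il17f by 4.90, Il10 by 4.61, Maf by 4.38 and Il21 by 4.09 (log2). Batf went the other way at -2.87, since its rise came early. Ccr6 had a difference of 0.88 (adjusted p = 0.385). In all 5186 genes had a different effect at the 2 times, with a log2 effect higher at 72 h than at 2 h for 2877 and lower for 2309. Most were lower, not higher, without TMM scaling (2849 against 2515) and in DESeq2 (2612 against 2525). Without course 2 the count was 2438, without course 3 it was 3085, and without course 1 it was 6886.

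Courses 4 to 6 asked what IL1b and IL21 add to IL6 and TGFb. From 24 to 72 h, cells given IL1b rather than IL21 had more transcripts of most NF-kB and IL-1 genes and of Il22. Il22 was higher by 2.67 ± 0.18 (adjusted p = 3.47e-19, mean of 3 times with 3 libraries each), and at 72 h stood at 25.9 ± 15.8 CPM with IL1b against 2.8 ± 1.4 CPM with IL21. Pdzk1ip1, a membrane adaptor gene, was up by 3.09 ± 0.23 (adjusted p = 3.13e-17), Ermn, a cytoskeletal gene, by 2.49 ± 0.29, Lum, a matrix gene, by 2.23 ± 0.32, Il1rn, the IL-1 receptor antagonist, by 2.20 ± 0.14, and Il9 by 1.96 ± 0.20. Il17a was higher by 1.05 ± 0.25 (adjusted p = 0.00242), at 638 ± 229 against 181 ± 56.7 CPM at 72 h, though its adjusted p was 0.0981 in DESeq2 and 0.0745 with a pseudocount of 0.1. Of 17 NF-kB and IL-1 genes 11 rose, with the NF-kB cofactor gene Nfkbiz (1.86 ± 0.10) and the inhibitor genes Tnfaip3 (0.98 ± 0.14) and Nfkbia (0.89 ± 0.12). Lower with IL1b than with IL21 were Angptl2, a secreted angiopoietin-like gene (-1.78 ± 0.22), Lgals3 (-1.61 ± 0.19), Cxcr5, the Tfh homing receptor (-1.44 ± 0.21), Pltp, a lipid transfer gene (-1.44 ± 0.18), Klf2, a quiescence factor (-1.33 ± 0.21), and Tox, a transcription factor of Tfh and exhausted cells (-1.02 ± 0.08). Serpinb1a, a protease inhibitor gene, was at -1.55 ± 0.28 (adjusted p = 0.106 without course 6) and Tbx21 at -1.11 ± 0.25 (0.0675 without course 6).

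The Th17 core list itself split, 5 genes higher and 5 lower of 16. Il22, Il24 (1.28 ± 0.13), Il17a, Ccr6 (0.64) and Batf (0.57 ± 0.09) were higher with IL1b, and Maf (-0.61), Ahr (-0.44), Il10 (-0.66), Il1r1 (-0.47) and Ccl20 (-0.45) were lower. Ccr6, Maf, Ahr, Il10 and Il1r1 had adjusted p of 0.152, 0.186, 0.126, 0.321 and 0.0913 without course 6, and Il1r1 0.19 without course 4. Ccl20 (adjusted p = 0.0419) lost its call without course 5 (0.318), without course 6 (0.753), in edgeR (0.217) and in DESeq2 (0.471). Il17f (0.50 ± 0.37, adjusted p = 0.447) did not pass, though with only the libraries compared in the fit its adjusted p was 0.00031. In that same fit Il10 (adjusted p = 0.0825), Tbx21 (0.0674) and Ccl20 (0.124) lost their calls. The Th17 pathogenic-associated list also split (5 higher, 7 lower of 16), as did the non-pathogenic-associated one (2 and 5 of 7). Cytokine receptors had 1 higher and 6 lower of 21, naive and quiescence genes 1 and 7 of 14, glycolysis 4 higher of 17, and stress genes 4 higher of 11. Adjusted over the list alone, NF-kB had 14 higher, Th17 core 5 and 8, pathogenic-associated 6 and 7, receptors 1 and 8, naive 2 and 8, glycolysis 6 higher and stress 6 higher. In camera the NF-kB list held with an estimated correlation (3.76e-19, then 0.00761), while naive (0.0013), glycolysis (0.00587), receptors (0.0142) and stress (0.0151) had adjusted p = 0.461, 0.546, 0.323 and 0.546 with an estimated correlation. In all 1699 of 14859 genes differed, 676 higher with IL1b and 1023 lower. Without course 5 the count was 1069 and without course 6 it was 458. Libraries of a course tracked each other at 72 h, and with a block for course at each time it was 3543.

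Adding IL1b to the IL21 cocktail was tested against the same IL21 libraries as IL1b in place of IL21. Pdzk1ip1 rose by 2.82 ± 0.23, Il22 by 2.42 ± 0.18, Il1rn by 2.11 ± 0.14, Il9 by 2.10 ± 0.20, Ermn by 2.10 ± 0.29 and Nfkbiz by 1.75 ± 0.10. Il17a was up by 0.88 ± 0.25 (adjusted p = 0.0186; 0.0753 without course 4, 0.339 without course 5, 0.204 in DESeq2, 0.196 with a pseudocount of 0.1). Angptl2 (-1.46 ± 0.22), Lgals3 (-1.38 ± 0.19), Pltp (-1.18 ± 0.18), the motor protein gene Myo6 (-1.16 ± 0.23) and Tox (-1.05 ± 0.08) fell. Serpinb1a was at -1.26 (adjusted p = 0.0646 without course 5 and 0.116 without course 6). With only the libraries compared in the fit, Myo6 (adjusted p = 0.0622), Serpinb1a (0.101) and Il17a (0.0518) lost their calls. Of 17 NF-kB genes 11 rose, and of 16 Th17 core genes 5 rose and 3 fell. Pathogenic-associated genes were 2 higher and 7 lower, non-pathogenic-associated 2 and 3, naive 1 and 5, receptors 1 and 4, glycolysis 1 higher, and no stress gene passed. Adjusted over the list alone, 15 NF-kB, 5 and 5 Th17 core, 5 and 7 pathogenic-associated, 2 and 5 non-pathogenic-associated, 4 glycolysis and 2 stress genes passed. NF-kB was at 4.7e-22 in camera (0.00299 with an estimated correlation), and glycolysis (0.0042), receptors, naive and stress genes (each 0.0424) had adjusted p = 0.661 with an estimated correlation. The count was 1008 (467 higher, 541 lower), 382 without course 5, 333 without course 6 and 2500 with a block for course at each time.

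Adding IL21 to the IL1b cocktail, by contrast, gave 0 called genes from 24 to 72 h in limma, edgeR and DESeq2. Of 14859 genes 213 had an unadjusted p under 0.05 in limma, fewer than the 0.05 share that chance gives. Libraries of a course tracked each other at 72 h, and a fit that leaves course out can then be too cautious. With a block for course at each time limma called 7. Th17 core genes lay between -0.25 and 0.20. Il17a stood at 467 ± 283 CPM at 72 h with both cytokines and 638 ± 229 CPM with IL1b alone, and Il22 at 19.9 ± 12.4 and 25.9 ± 15.8 CPM. Camera called TGF-beta and naive genes (each 0.00164) and non-pathogenic-associated genes (0.0489) as lists, with adjusted p = 0.735, 0.735 and 0.755 with an estimated correlation.

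**Figure D4:**
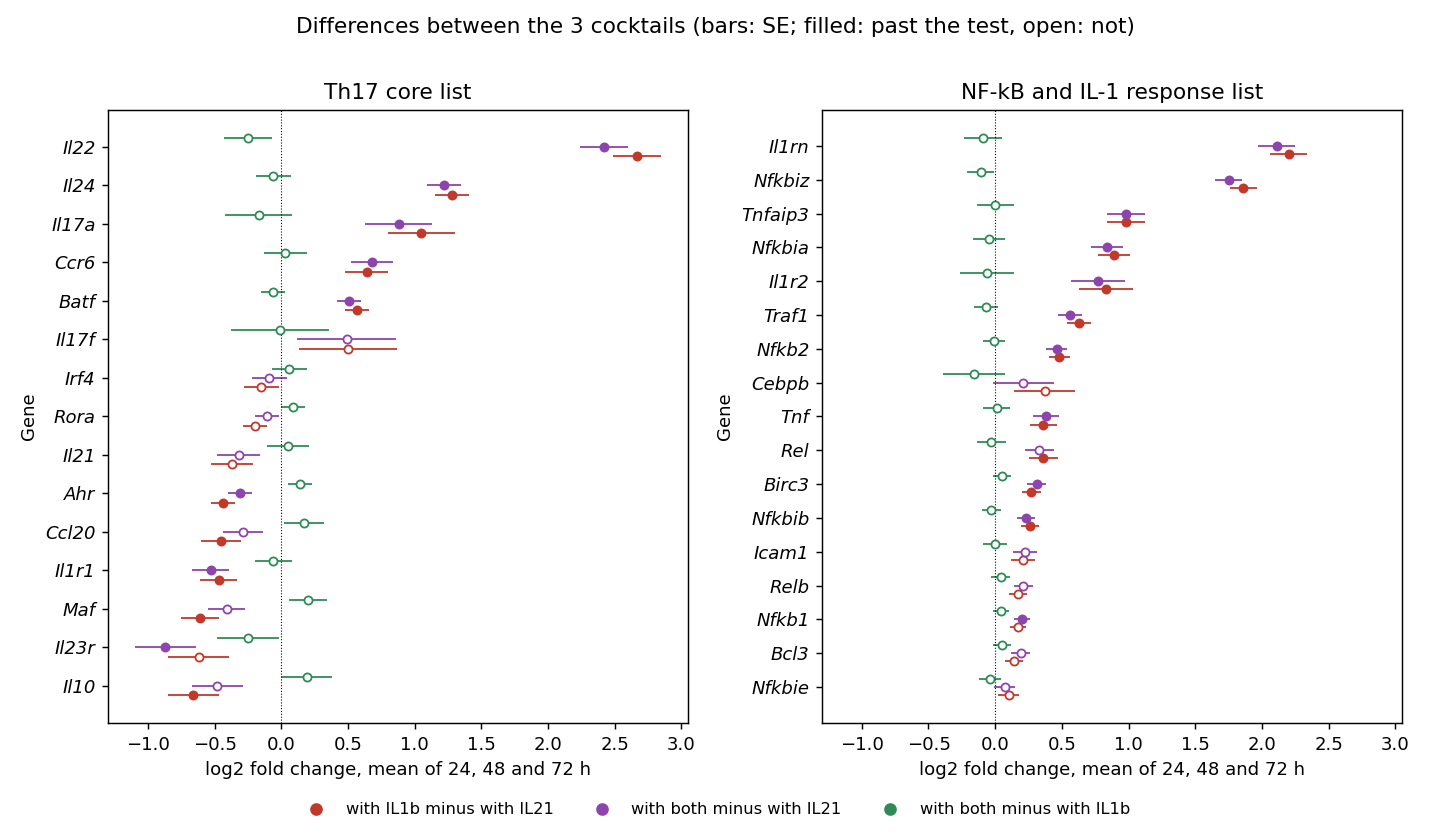
Log2 differences (mean of 24, 48 and 72 h ± SE) of 15 of the 16 Th17 core genes and the 17 NF-kB and IL-1 genes in the 3 comparisons among cocktails of courses 4 to 6, filled where the limma test passed. IL1b against IL21 and both against IL21 use the same IL21 libraries, and for both against IL1b the Th17 core genes lie between -0.25 and 0.20.

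Before 24 h few genes differed between cocktails. From 0.5 to 2 h the IL1b cocktail had more Bcl6, a Tfh regulator, than the IL21 cocktail (0.50 ± 0.09, adjusted p = 0.00204; 0.335 without course 5, 0.12 without course 6). Daxx, a chromatin gene, was at -0.36 ± 0.07 (0.601 without course 4, 0.626 without course 6) and Oas1b, an antiviral gene, at -0.41 ± 0.09 (0.247, 0.545 and 0.626 without courses 4, 5 and 6). The other 3 of the 6 genes, chosen after their values were seen, were Ifi205 (-0.36), 4930594C11Rik (-0.42) and RP24-547J21.3 (-0.75). Both cytokines against IL1b in that window gave 70 genes (63 higher, 7 lower), among them Lif, a cytokine of the IL-6 family (0.89 ± 0.21, adjusted p = 0.0224; 1 without course 6), Frmd4b, a scaffold gene (0.73 ± 0.12, adjusted p = 0.000646; 0.131 without course 4, 0.377 without course 6) and Smim19 (-0.26 ± 0.07, adjusted p = 0.0416; 0.47 without course 4, 1 without course 6). With only the libraries compared in the fit, Daxx (adjusted p = 0.531), Oas1b (0.0515), Lif (0.149), Frmd4b (0.209) and Smim19 (0.207) lost their calls. Both against IL21 gave 0 genes in limma, 1062 at an unadjusted p under 0.05, and 0 in edgeR and DESeq2. From 4 to 12 h Gbp2, an interferon-induced GTPase gene, was lower with IL1b than with IL21 and higher with both than with IL1b, at -0.60 ± 0.14 (adjusted p = 0.0451; 0.133, 0.413 and 0.654 without courses 4, 5 and 6) and 0.63 ± 0.14 (adjusted p = 0.0384; 0.125, 0.52 and 0.687). Stap1, a signalling adaptor gene, was at 0.46 ± 0.08 (0.0918 without course 5, 0.453 without course 6) and -0.43 ± 0.08 (0.0932 and 1). Both against IL21 gave 1 gene, the B cell coreceptor gene Cd72 (0.64, adjusted p = 0.000241, chosen after its value was seen).

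IL1b against IL21 thus gave 6 genes from 0.5 to 2 h (2 without course 4, 2 without course 6) and 34 from 4 to 12 h (18 higher, 16 lower; 7 without course 5, 3 without course 6). A block for course gave 15 and 53, and one at each time 156 and 238. Both against IL1b gave 70 (9 without course 4, 166 without course 5, 1 without course 6) and 20 (13 higher, 7 lower; 2 without course 5, 0 without course 6, 32 with the block), and 472 and 190 with the block at each time. Both against IL21 gave 2 without course 5 in the first window, and in the next 0 without course 5, 2 with the block and 23 with the block at each time. Without TMM scaling 54.2% of the calls for both against IL1b from 4 to 12 h were higher in place of 65%.

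Cocktails could be set against IL6 and TGFb alone only across the sets of courses, relative to each set's own 0 h group, so a difference between the sets that appeared after 0 h stays in these values. On this measure, from 24 to 72 h IL1b added 1.94 ± 0.21 of Nfkbiz, an inducible NF-kB cofactor (adjusted p = 1.98e-11), and 1.92 ± 0.27 of Sh3bp4, an endocytosis gene (adjusted p = 3.15e-07). With both cytokines these were 1.84 ± 0.21 (adjusted p = 1.55e-10) and 1.88 ± 0.27. Il9 was up by 2.29 ± 0.41 with IL1b (adjusted p = 0.000134) and 2.42 ± 0.41 with both (4.17e-05), but edgeR gave 0.988 and 0.928 and DESeq2 0.919 and 0.83. Il1rn rose with both by 1.59 ± 0.28 (adjusted p = 9.45e-05; 0.69 in edgeR, 0.477 in DESeq2). Ermn was up with IL1b by 1.95 ± 0.46 (adjusted p = 0.0146). Its adjusted p was 0.0647, 0.094, 0.177, 0.241 and 0.128 without courses 1, 2, 3, 5 and 6, and 0.956 in edgeR and 0.877 in DESeq2. In limma it was 0.155 with a pseudocount of 0.1 and 0.133 with only the libraries compared. Lower were Ramp1, a neuropeptide receptor subunit (-1.07 ± 0.22, adjusted p = 0.00146), with IL1b, and Gata3 (-0.98 ± 0.18, adjusted p = 0.000445), with both. Synpo, a cytoskeletal gene, was at -1.30 ± 0.28 with IL1b (0.0526 without course 3, 0.0667 without course 6) and -1.33 ± 0.28 with both (0.0849 without course 6). Cd24a, a surface marker gene, was at -1.14 ± 0.24 with IL1b (0.051 without course 6) and -1.11 ± 0.24 with both (0.154 without course 6). In edgeR the adjusted p of Synpo was 0.239 and 0.234 and that of Cd24a 0.112 and 0.133. IL1b changed 98 of 15328 genes (55 higher, 43 lower), 179 without course 4, 58, 57 and 36 without courses 2, 5 and 6, and 154 with a course block. Both changed 80 (48 and 32), 132 without course 4, 49 without course 2 and 29 without course 6. IL21 changed 0 in limma and edgeR and 6 in DESeq2, and in limma 4 without course 1 and 1 without course 3. In limma 633 genes had an unadjusted p under 0.05, fewer than the 0.05 share that chance gives. For IL1b 56.1% of calls were higher, 67.6% without TMM scaling and 73% with RLE scaling.

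The 0 h groups of the sets were compared to see how far the naive cells started alike. Ribosomal protein copies differed: Rps13-ps1 was 1.54 ± 0.29 higher in courses 4 to 6 (adjusted p = 0.00222), Rpl19-ps11 1.33 ± 0.29 (0.0111), Rps27rt 1.33 ± 0.29 (0.0154) and Rpl31-ps8 1.20 ± 0.28 (0.0231). Without course 2 these adjusted p were 0.223, 0.825, 0.803 and 0.965, without course 5 they were 0.154, 0.254, 0.25 and 0.336, and without course 6 they were 0.0694, 0.188, 0.188 and 0.323. Without course 3 the last 3 were at 0.148, 0.154 and 0.237. Of 23 genes called, 22 were higher and 19 carried names of predicted genes or pseudogenes. Of the rest, chosen after their values were seen, Xist, the X inactivation RNA, was at -3.24 ± 0.54 (adjusted p = 0.000296), the Mediator gene Med21 at 0.55 ± 0.11 and Anapc15, of the anaphase complex, at 0.38 ± 0.09. The count was 41 without course 1 or 4, 2 without course 2, 1 without course 5 and 0 without course 6. Of the calls 95.7% were higher, 85.2% without TMM scaling and 84% with RLE scaling.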

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

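Of the tests in this part, the exchange and time-point tests of the course 1 libraries, the myeloid and 0 h tests of the interferon genes, and all counts over other splits of the libraries were chosen only after the result was seen.

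The effect of IL6 and TGFb was not the same at 72 h as at 2 h for 5186 genes by the direct limma test, and this difference between times is why they are listed. Among Th17 core genes the effect grew most for the receptor gene Il23r (6.49 on the log2 scale), the chemokine gene Ccl20 (6.36) and the cytokine gene Il17a (6.21). It also grew for Il17f (4.90), Il10 (4.61), Maf (4.38), Il21 (4.09), Ahr (4.00), Rora (3.94), Il24 (3.74), Irf4 (3.24), Il1r1 (3.21) and Il22 (1.86). Batf, whose product opens chromatin early in Th17 cells, shrank (-2.87), as its rise was larger at 2 h than at 72 h. Of 100 splits only the real one, 1 of 100, gave as many genes. These splits exchanged libraries at both times, so they test for no effect at either time. Whether chance gives a difference between the times they cannot decide. The highest other split gave 5032 and kept the true groups at 72 h.

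At 0 h, 2 of 37 values tested (genes named against 0 h and the library total) had a library far from the other 5, in each case that of course 5. These were the interferon genes Usp18 (43.2 CPM against a median of 29.4, gap 0.831 of the range) and Irf7 (132 against 102, gap 0.787), where 6 libraries must exceed 0.625. Chance gives about 1 in 20, so 2 of 37 is near the number it gives, and no explanation was tested.

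Interferon response genes were higher early with IL6 and TGFb, with Gbp2 at 3.64 ± 0.39 and Rtp4 at 3.36 ± 0.41 at 2 h. RNA from myeloid cells is argued against by the myeloid markers, whose median was -0.06. Because the same genes fell after stimulation, IL6 and TGFb may have slowed the loss of transcripts present at 0 h rather than started new ones: 5 of 18 were above and 7 below their 0 h level, so these cannot be told apart from the levels alone. Signalling by IL6 through STAT proteins shared with interferon receptors is a biological explanation that was not tested.

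In the course 1 culture without cytokines, cells at 72 h still looked activated. Il2 stood at 312 CPM against 3.88 and 2.08 CPM in courses 2 and 3, and Lag3, an inhibitory receptor gene, at 200 against 5.16 and 4.88 CPM. The 48 and 72 h libraries lay 0.644 and 0.946 (root mean square log2) from the mean of courses 2 and 3, where the highest distance of the other course 1 libraries was 0.374. Library size is argued against, since thinning to equal depth left 0.951 at 72 h, as is an exchange with the IL6 and TGFb library, since only 4 of 16 Th17 core genes lay nearer to that condition. Another time point as a whole is argued against by a nearest distance of 0.66, though the 48 h library was nearest to 24 h (0.477), so a culture that lagged behind, which was not tested further, stays open.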

How the results depend on the processing

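Of the settings in this part, no TMM scaling, the pseudocounts, edgeR, the fit without the course 1 libraries, the course block at each time and the course block fitted to only the libraries compared were chosen only after the result was seen. Il17a, Il23r and the other Th17 core genes named were called higher at 72 h in each setting tried there, except Ccr6 (log2 0.11 in edgeR and 0.08 in DESeq2, against 1.36) and Batf (adjusted p = 0.215 without course 2). Of 198 gene values, all 198 kept direction and call with RLE scaling and with a pseudocount of 1, 197 without TMM scaling, 193 without a filter, 187 with a pseudocount of 0.1, 190 in DESeq2 and 183 in edgeR, 194 of 194 with a course block and 50 of 50 with a course block at each time. With only the libraries compared 176 of 197 did. Leaving out course 1, 2 or 3 kept 147, 134 and 137 of 148, and leaving out course 4, 5 or 6 kept 60, 54 and 40 of 68. No gene value reversed in any of these settings. Among 26 counts of genes, 26 stayed within 1.5 times with RLE scaling, 24 without TMM scaling, 25 with a pseudocount of 1, 23 with 0.1, 22 in edgeR, 22 in DESeq2, 16 without a filter and 9 with only the libraries compared, 20 of 25 with a course block and 1 of 9 with a course block at each time. All 4 counts stayed within 1.5 times without the course 1 libraries at 48 and 72 h. Depth was not the limit for named genes, whose mean was at least 5 CPM with at least 16 M reads per library, but genes under 1 CPM were left out of all limma and DESeq2 fits with the filter; edgeR, with its own, tested 17640 to 18574 genes.

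The counts that moved by more than 1.5 times were these. With only the libraries compared in the fit, no cytokines at 72 h against 0 h gave 6290, and IL6 and TGFb against no cytokines gave 21 at 0.5 h, 1254 at 4 h, 1779 at 6 h, 2539 at 12 h, 4841 at 48 h, 2966 at 72 h and 2939 for 72 minus 2 h. Under that setting both against IL21 gave 11 at 4 to 12 h and 539 at 24 to 72 h, both against IL1b 6 at 0.5 to 2 h and 134 at 4 to 12 h, and IL1b against IL21 1, 219 and 1017 in the 3 windows. IL1b relative to 0 h gave 171 and the 0 h groups 0 (limma). Such a fit has fewer samples to estimate the spread, and it takes the spread from the groups compared alone, not from all groups. For IL6 and TGFb the counts moved both ways, up at 4, 6 and 12 h and down at 0.5, 48 and 72 h. Without a filter IL6 and TGFb at 0.5 h gave 158, both against IL21 at 0.5 to 2 h 15, both against IL1b 11 at 4 to 12 h and 8 at 24 to 72 h, and IL1b against IL21 41 at 0.5 to 2 h and 17 at 4 to 12 h. The comparisons relative to 0 h then gave 243 for IL1b, 24 for IL21 and 162 for both, and the 0 h groups 211. A course block gave 2 for both against IL21 at 4 to 12 h, 32 for both against IL1b at 4 to 12 h, 15 and 53 for IL1b against IL21 at 0.5 to 2 h and 4 to 12 h, and 154 for IL1b relative to 0 h. A course block at each time gave 23 and 2500 for both against IL21 at 4 to 12 h and 24 to 72 h, 472, 190 and 7 for both against IL1b in the 3 windows, and 156, 238 and 3543 for IL1b against IL21. The block with only the libraries compared gave 353 at 0.5 h, 2322 at 1 h, 4149 at 2 h, 2557 at 4 h and 4482 at 12 h. A pseudocount of 0.1 gave 2 for both against IL21 at 4 to 12 h and 59 and 48 for IL1b and both relative to 0 h, and a pseudocount of 1 gave 17 for IL1b against IL21 at 0.5 to 2 h. DESeq2 gave 3 for both against IL21 at 4 to 12 h, 18 for IL1b against IL21 at 0.5 to 2 h, and 57 and 6 for IL1b and IL21 relative to 0 h. In edgeR both against IL1b gave 12 at 4 to 12 h, IL1b against IL21 3 at 0.5 to 2 h, and IL1b and both relative to 0 h 33 and 30. Without TMM scaling both against IL1b at 0.5 to 2 h gave 41 and IL1b against IL21 18. Without the 0 h term the cocktails against IL6 and TGFb gave 1989, 691 and 1553 for IL1b, IL21 and both. The cause was not tested.

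Leaving out 1 course gave these lowest and highest counts. For IL6 and TGFb they were 43 and 65 at 0.5 h, 533 and 1135 at 1 h, 673 and 1986 at 2 h, 229 and 751 at 4 h, 278 and 761 at 6 h, 736 and 1492 at 12 h, 2326 and 3723 at 24 h, 4726 and 8481 at 48 h, 3866 and 8250 at 72 h, and 2438 and 6886 for 72 minus 2 h. Both against IL21 gave 0 and 2, 0 and 1, and 333 and 948 in the 3 windows. Both against IL1b gave 1 and 166 at 0.5 to 2 h and 0 and 17 at 4 to 12 h, and IL1b against IL21 gave 2 and 4, 3 and 35, and 458 and 1405. Relative to 0 h, IL1b gave 36 and 179, IL21 0 and 4 and both 29 and 132, and the 0 h groups gave 0 and 41. With an estimated correlation the number of lists called was 0 at 2, 24 and 72 h without cytokines (4, 7 and 8 at the preset correlation in camera), 3 in place of 9 for IL6 and TGFb at 2 h and 7 in place of 12 at 72 h, 1 in place of 5 for both and for IL1b against IL21 at 24 to 72 h, and 0 in place of 3 for both against IL1b.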

Other observations

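Of the tests in this part, all counts over other splits of the libraries were chosen only after the result was seen, and the tests of the ribosomal pseudogenes were written before theirs. Across all conditions at 72 h, with cocktails and IL6 with TGFb in different courses and so not tested against each other here, Il17f was abundant in each Th17 condition. It stood at 916 ± 361 CPM with IL6 and TGFb, 1930 ± 289 CPM with IL1b added, 1120 ± 227 CPM with IL21 and 1760 ± 74.2 CPM with both (SD, n = 3). Il9, a cytokine gene of mast cell help, stood at 2.76 ± 1.65, 53.5 ± 14.8, 6.78 ± 3.5 and 56.7 ± 24.9 CPM in the same order. Il24, an IL-10 family cytokine gene, stood at 7.75 ± 3.26, 57.3 ± 20.3, 11.4 ± 7.23 and 38.3 ± 8.58 CPM. Il23r stood at 59.9 ± 4.61, 29.6 ± 12.5, 39.7 ± 25.6 and 23.2 ± 16 CPM, with overlapping SDs among the cocktails. Il21 stood at 692 ± 70.6, 422 ± 4.3, 531 ± 143 and 427 ± 51.9 CPM. Ifng, the Th1 cytokine gene, was under 1 CPM in each of these conditions, at 0.107 ± 0.0127 CPM with IL6 and TGFb.

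The 8 ribosomal protein pseudogenes called between the 0 h groups, copies of genes such as Rps13 and Rpl19, were higher in the naive cells of courses 4 to 6. Their median log2 difference was 1.31. They were picked by that call, so this median had to be large and does not describe ribosomal pseudogenes as a class. The parent genes of these 8 differed by a median of 0.1, which argues against more ribosomal protein transcripts in those cells as the source. Thinning to equal depth left 1.26 for the 8, which argues against library size. At the later times the same pseudogenes differed between the sets by a median of 1.21 (0.9 to 1.41), so reads shared between genes and pseudogenes may have been assigned differently in the sets. The sets differ in courses at every time, so this stays a hypothesis.

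Xist, expressed from an inactive X chromosome, had medians of 2.56, 5.95 and 5.41 CPM in courses 1, 2 and 3 and 0.19, 0.156 and 0.249 CPM in courses 4, 5 and 6. The Y-linked gene Ddx3y had medians from 107 to 121 CPM in all 6 courses. Of other Y-linked genes, Uty had medians of 29.9, 30.3 and 26.1 against 20.2, 21.6 and 20.4 CPM. Eif2s3y had 84.9, 78.7 and 83.8 against 76, 72.5 and 72.2 CPM, and Kdm5d 57.8, 56.7 and 60.7 against 57.1, 52.4 and 52.2 CPM. These medians pool culture conditions that differ between the sets.

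Other splits of the libraries bear on how many genes the calls for Il17a, Il22 and their like stand among. For 3 against 3 libraries the 10 splits are too few for a share under 0.05. There no cytokines against 0 h gave 10166, 10681 and 9603 genes at 2, 24 and 72 h and at most 1, 1 and 1968 in another split. IL6 and TGFb gave 646, 677, 1399 and 3844 at 4, 6, 12 and 24 h and 0 in each other split (limma). At 48 and 72 h they gave 7791 and 6803, with 3394 and 5285 in the split that exchanged the course 1 libraries. The 0 h groups gave 23 and at most 7. At 1 and 2 h, 1170 and 1826 genes stood against 36 and 194, and at 0.5 h 89 stood against 1513, with 3 of 10 splits as large; these higher splits did not part the libraries of each course, so they follow a structure by course. Where each course was parted, as in the real groups, other splits gave 0 at 0.5, 1, 2, 4 and 12 h (limma).

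Among cocktails 100 splits were counted. They exchanged libraries at each time on its own, so they do not cover deviations that a culture carries over several times. With that limit, the share was under 0.05 for both against IL1b at 4 to 12 h (20 genes, 1 of 100 splits as large, highest other 1). The same holds for IL1b against IL21 at 4 to 12 h (34, 1 of 100, 8) and 24 to 72 h (1699, 1 of 100, 1510). For IL1b and both relative to 0 h the share was also under 0.05 (98 and 80, 1 of 100 each, 25 and 52). There the real split also parts the sets of courses, so a difference between the sets that arose in culture is not excluded. For both against IL21 at 24 to 72 h (1008 genes) 4 of 100 splits were as large, with 1359 in the highest other. That share lies too near 0.05 to settle chance from these splits. For both against IL21 at 4 to 12 h the count of 1 gene was tied by other splits (4 of 100 in all, highest other 1), so it decides nothing. At 0.5 to 2 h these splits did not exclude chance for both against IL1b (70; 6 of 100, highest other 243) or IL1b against IL21 (6; 11 of 100, 578). The counts of 0 in limma for both against IL21 at 0.5 to 2 h, both against IL1b at 24 to 72 h and IL21 relative to 0 h were met by 100 of 100 splits, the highest of which gave 716, 1088 and 9 genes. What structure of the libraries, if any, gave splits with several times the real count was not tested. Since libraries of a course tracked each other at some times, such as 4 and 72 h, the cocktails were also split only within a course and time. From 24 to 72 h, of 100 such splits the highest other gave 266 genes for both against IL21 (1008 real), 1222 for IL1b against IL21 (1699) and 0 for both against IL1b (0). With a block for course at each time the highest other gave 1146 (2500 real), 2978 (3543) and 216 (7 real, met by 19 of 100 splits). From 4 to 12 h the highest other gave 4 for both against IL1b (20 real) and 10 for IL1b against IL21 (34). With the block it gave 97 (190) and 105 (238), and in each case 1 of 100 splits was as large. These splits also exchanged each time on its own, so deviations carried over several times are not excluded. Without course 6 the counts of 20 and 34 were 0 and 3. For both against IL21 it gave 2 (1 real, met by 4 of 100 splits), and with the block 5 (23 real, 1 of 100). From 0.5 to 2 h the splits did not agree. Without the block 4 of 100 were as large for both against IL1b (70 real, highest other 528) and 4 of 100 for IL1b against IL21 (6, 349), but with it 19 of 100 (472, 2117) and 7 of 100 (156, 2388), so chance is left open in that window. For both against IL21 in that window other splits gave up to 196 genes, and 1792 with the block.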
